A study of Mus musculus with 10 samples.

How the data were processed

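The series combined expression arrays and ChIP-on-chip arrays of mouse forelimb buds at embryonic day 10.5. Expression was measured on 6 Affymetrix arrays, from the proximal and the distal segment of buds in 3 arms: control, Ring1A/B double knockout (dKO) and retinoic acid (RA). ChIP-on-chip was measured on 4 Agilent arrays, with H3K27me3 or RING1B precipitated from pooled whole buds of untreated wild-type embryos. Each of the 10 groups held 1 array, so no difference between groups has a replicate check and no p-value was computed. The number of arrays limits the precision.

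The deposited expression values are signal intensities on a linear scale, made with MAS5 per the submitters' processing notes. On every array the 2% trimmed mean over all 45101 probe sets was 500.0, which was tested on the values. The deposited ChIP value tables hold log2 ratios of ChIP over input, not centred on 0; setting them against the scanner values gave their scale and direction. The spot intensities of the ChIP arrays were extracted with Agilent Feature Extraction 10.1.1.1, which subtracted background, removed a spatial trend and applied a linear dye normalization, per the file headers. The LogRatio column is the log10 of red over green processed signal per the file headers, and the labels give Cy5 (red) to the ChIP fraction and Cy3 (green) to input. Both DNA fractions were amplified with T7 RNA polymerase before labelling, per the labels' protocols. The genome build of the probe coordinates is not given in the sources used here. It may not be GRCm38.p6, the assembly of the RefSeq table used here, since 599 probes on 7 chromosomes lay beyond the last gene end of that table. Probes can lie past the last gene in the same build too, and chromosome ends were not compared, so this does not settle it.

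The comparisons, thresholds, gene lists and most alternatives were fixed before the data were examined. They were written for genes, but the files do not pair the Affymetrix probe sets with genes, and the ChIP probes carry coordinates only. The unit of the expression results is therefore the probe set and that of the ChIP results the tiled region. The 20 gene lists, the check of the targeted genes, the median over a gene's probe sets and the join of ChIP to expression were not run. The rule for named genes was applied to probe sets, and IDs are printed for the dKO comparison only, 2 per direction: those above the floor on all 4 arrays that were highest or lowest by the smaller of the 2 segments' log2 ratios.

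For expression, 64 control probe sets were set aside and 45037 were tested. Signals under the floor, the 40th percentile of all signals (33.3), were set to it before taking log2. A probe set counted as changed when it differed at least 2-fold in the same direction in both segments, and as proximal-high or distal-high when the segments of an arm differed at least 2-fold. Overlaps are given beside n1 × n2 / N, the overlap of independent lists. Because dKO and RA were set against the same control arrays, 100 simulated data sets of unchanged arms sharing those arrays were drawn. The simulated noise came from the difference between the proximal and distal dKO ratios divided by 2, taken in 20 bins of mean expression. Comparisons that share no array are given beside those that do. A set of probe sets was described by its median log2 ratio, or its share at 2-fold, and by the percentile of that value among 10000 random lists matched on mean expression in 20 bins. Mean expression was taken over all 6 arrays, including those that defined the set. Correlations and set medians between arms used the 23428 probe sets above the floor on all 6 arrays.

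For ChIP, control spots, spots with outlier flags and probes without a position were left out, which kept 472862 probes. The log2 ratio of processed signals was centred on each array's median. Before centring, the medians were -0.16 and 0.02 for H3K27me3 and -0.11 and -0.12 for RING1B, for array 1 and array 2 of the probe set. Probes whose starts lay at most 1500 bp apart formed a tiled region, and no region was split between the 2 arrays. The score of a region was the highest mean of 3 consecutive probes spanning at most 1500 bp; 16969 regions had such a window. A region was called enriched at a log2 of 1. A threshold of 3 was added after seeing the data, because depleted windows outnumbered enriched ones at 1. Regions co-enriched at 3 were joined into domains over gaps of at most 20 kb. Intervals of shares are exact binomial (Clopper-Pearson, 95%) and treat regions or probe sets as independent, which neighbours are not.

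Alternatives for expression were quantile normalization, a common median, floors at the 20th (10.1) and 60th (145.2) percentile, and a 3-fold threshold. Alternatives for ChIP were normexp background correction with an offset of 50, the authors' value table, windows of 5 probes spanning at most 2500 bp, a threshold of 1.5, and probes well above background in both channels only. Normexp was run on median spot signals, because no column of mean spot signals was in the files used here. The distal RA arrays alone and the ChIP threshold of 3 were added after seeing the data.

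The steps were tested on simulated data. For dKO against control, in a simulation of 45037 probe sets, the 2-fold rule in both segments recovered 0% of probe sets raised 1.5-fold, 20.0% of those raised 2-fold, 96.0% of those raised 3-fold and 98.0% of those raised 4-fold, with 50 probe sets of each. The raised probe sets were drawn only from those over 2-fold above the floor on all 6 arrays. The rule called 0 of 44837 unchanged probe sets higher and 3 lower. The simulated noise came from floored ratios, which are compressed at dim signals, so these counts say little about dim probe sets. In the tiling of 16969 regions, with independent noise of SD 1 per probe, 6 probes were raised in 200 regions. A window of at least 3 was found in 0% of them at a rise of log2 1, 8.5% at 2, 81.0% at 3 and 100% at 4. Neighbouring probes of the real arrays are correlated, which this noise is not. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.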

Results

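Forelimb buds of mouse embryos at embryonic day 10.5 were profiled to ask how Polycomb group proteins and retinoic acid signalling act on patterning along the proximal-distal axis, the axis from shoulder to fingertip. RING1A and RING1B are the catalytic subunits of Polycomb repressive complex 1, which represses developmental genes, and H3K27me3 is the histone mark placed by Polycomb repressive complex 2. Proximal and distal segments were measured separately in control buds, in dKO buds that carried Prx1-Cre (a Cre driver active in limb mesenchyme) with a Ring1A-null and floxed Ring1B genotype, and in buds of embryos whose mothers received all-trans RA at 100 mg/kg at E10.25. The labels describe the control arrays as wild type in one field and Ring1A-null in another, and the series design speaks of Ring1A knockouts. The control and dKO arrays are labelled C57BL/6 and the RA arrays BDF1 and wild type, so RA against control also differs in strain and, if the control buds were Ring1A-null, in Ring1A genotype. In that case dKO against control measures the loss of RING1B on a Ring1A-null background, and otherwise that of both proteins. Each segment and arm had 1 array, and each antibody had a pair of arrays that cover different regions.

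The 6 expression arrays held similar shares of probe sets above the floor, from 57.7% on the distal control array to 62.1% on the distal dKO array. Their correlations, across 23428 probe sets that are not independent replicates, ran from 0.924 (proximal RA with distal dKO) to 0.985 (the 2 dKO arrays). The proximal RA array correlated at most at 0.943 with any other array, and its brightest signal was 26458 against 14434 to 16620 on the others. The bioB spike-in controls, added to every sample, had a median signal of 169.3 and 155.1 on the proximal and distal RA arrays and 1381 to 1503 on the other 4. The bioC and bioD controls differed less, from 2382 to 2870 and from 6696 to 7942.

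The dKO buds gained signal at many more probe sets than they lost it at. In both segments, 691 probe sets were at least 2-fold higher in dKO than in control and 47 were at least 2-fold lower. Independent lists of the same sizes would share 38.9 and 0.746. The proximal segment alone had 1145 higher and 193 lower, and the distal segment 1532 and 174. The change was shared between segments: across 23428 probe sets the proximal and distal log2 ratios, which share no array, correlated at 0.515 (Pearson) and 0.349 (Spearman). The segments are not replicates. A difference other than genotype between the dKO and control samples could appear in both, so this sharing does not tie the change to the dKO.

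Of the 691 higher probe sets, 163 were at or below the floor on both control arrays, so they were called from signals that control buds did not clearly show, and 412 were above the floor on all 4 arrays. Those 412 had a median 2.74-fold rise in the proximal and 2.98-fold in the distal segment. The 42 lower probe sets above the floor on all 4 arrays had a median 2.98-fold fall in the proximal and 3.00-fold in the distal segment. Probe set 1418178_at had signals of 43.8 and 59.1 in proximal and distal control buds and 632.2 and 785.9 in dKO, 14.4-fold and 13.3-fold higher. Probe set 1453202_at was 13.1-fold and 15.5-fold higher. Probe set 1420357_s_at had signals of 407.5 and 445.7 in control and 36.7 and 35.4 in dKO, 11.1-fold and 12.6-fold lower, and 1418934_at was 7.84-fold and 7.31-fold lower. The floor at the 60th percentile (145.2), which lies above the dimmer signals, gave smaller log2 ratios: 2.12 and 2.44 for 1418178_at, from 3.85 and 3.73, and -1.49 and -1.62 for 1420357_s_at, from -3.47 and -3.65. The files do not pair these IDs with genes. Scaling to a common median gave 453 higher and 90 lower, a share higher of 83.4% against 93.6%, and the floor at the 60th percentile gave 179 and 26. With 1 array per group, none of these differences could be set against a replicate spread.

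**Figure D1:**
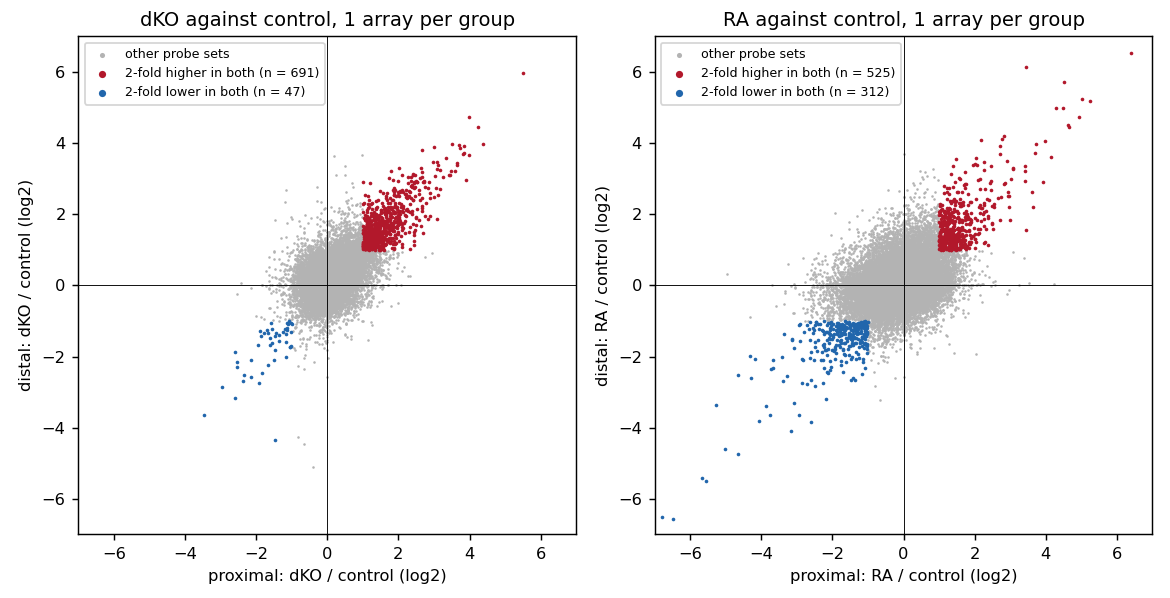
Log2 ratio of each probe set in the proximal (horizontal axis) and distal (vertical axis) segment, for dKO against control on the left and RA against control on the right, with 1 array per group; points are probe sets and colours mark those at least 2-fold higher or lower in both segments. The dKO points extend mostly to the upper right (691 higher, 47 lower), while the RA points extend both ways (525 higher, 312 lower).

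RA-treated buds differed from control in both directions. In both segments, 525 probe sets were at least 2-fold higher and 312 at least 2-fold lower, where independent lists would share 65.9 and 40.7. The proximal segment had 1557 higher and 2489 lower probe sets, and the distal segment 1905 and 736, so the excess of lower probe sets was on the proximal side. The probe set that ranked highest by the smaller of its rises in the 2 segments had signals of 34.5 and 45.4 in proximal and distal control and 1059 and 1217 in RA, 30.7-fold and 26.8-fold higher, or log2 ratios of 4.94 and 4.74 that fell to 2.87 and 3.07 with the floor at the 60th percentile. The one that ranked lowest in the same way had 3171 and 3275 in control, 98.7 and 135.5 in RA, and 2926 and 2837 in dKO.

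The proximal and distal RA ratios correlated at 0.368 (Pearson) and 0.298 (Spearman) across 23428 probe sets. Strain, and by some of the labels Ring1A genotype, changed together with RA, and the bioB controls of the RA arrays were dimmer, so no part of these differences can be assigned to RA alone. The split moved from 525 higher and 312 lower to 451 and 450 with a common median, and the distal arrays alone gave 1905 and 736.

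The dKO and RA changes overlapped in part. Of those changed in both segments, 30 of the 691 higher in dKO were also higher in RA and 13 of the 47 lower were also lower, where independent lists would share 8.06 and 0.326. Both comparisons used the same control arrays, and part of the excess may come from them. Simulated unchanged arms shared 0, but with averages of 0.23 to 0.39 calls per arm and direction they had almost none to share, so they do not show how large that part is. Their log2 ratios correlated at 0.258 in the proximal and 0.282 in the distal segment, with covariances of 0.0727 and 0.0706 against 0.0420 and 0.0420 in the simulation, which gave correlations of 0.50. Across segments, with no array in common, the correlations were 0.0104 (dKO proximal with RA distal) and 0.0232 (dKO distal with RA proximal), with covariances of 0.0023 and 0.0073. Under quantile normalization these correlations were -0.0319 and -0.0039, so they have no settled sign.

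Set against matched lists, overlaps without a shared array went the same way only in part. Of the probe sets 2-fold higher in dKO distal, 11.3% were also 2-fold higher in RA proximal, against a median of 7.96% in matched random lists. Of those higher in dKO proximal, 8.03% were higher in RA distal, against 11.97% in matched lists. Of those lower in dKO distal, 21.3% were lower in RA proximal against 10.34%, and of those lower in dKO proximal, 11.9% were lower in RA distal against 4.15%. In the opposite direction, 9.14% of those higher in dKO distal were lower in RA proximal (9.92% in matched lists) and 7.25% of those higher in dKO proximal were lower in RA distal (4.02%), while 5.17% of those lower in dKO distal were higher in RA proximal (6.90%) and 11.9% of those lower in dKO proximal were higher in RA distal (10.9%). Probe sets lower in dKO proximal were thus as often higher as lower in RA distal. For the same direction the percentiles among 10000 matched lists were 100, 0, 100 and 100. Against independent lists, which are not matched on expression, all 4 overlaps were larger: in the same order, 173 probe sets against 52.96, 92 against 48.4, 37 against 9.62 and 23 against 3.15. The overlap of dKO proximal with RA distal is thus below one reference and above the other.

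Proximal and distal segments of control buds differed at least 2-fold at 483 proximal-high and 358 distal-high probe sets. The dKO buds had 235 proximal-high and 346 distal-high probe sets, and the RA buds 1296 and 2578. The strongest proximal-high probe set of control buds had signals of 2018 and 160.4 in proximal and distal control, 2370 and 1367 in dKO and 1804 and 458.1 in RA. The next had 1845 and 163.0 in control, 827.5 and 1046 in dKO and 587.3 and 338.0 in RA. The strongest distal-high probe set had 43.6 and 1148 in control and 705.5 in distal RA, and was under the floor on both dKO arrays and on proximal RA. The next had 92.7 and 2141 in control, 104.4 in distal dKO, under the floor in proximal dKO, and 39.1 and 1431 in RA.

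Among probe sets above the floor on all 6 arrays, sets defined by a segment difference in control or dKO buds had medians of the same direction in the other arms. The 333 proximal-high probe sets of control buds that were above the floor on all 6 arrays had a median proximal over distal log2 ratio of 0.43 in dKO and 0.76 in RA, and the 234 distal-high ones -0.59 and -1.04. These are 333 of 483 and 234 of 358. The rest, which include any that fell under the floor in another arm, were left out. Among them were the 2 strongest distal-high probe sets of control buds. The 119 proximal-high probe sets of dKO buds had a median of 0.74 in control, and the 196 distal-high ones -0.40. In RA these 2 sets had 0.75 and -0.85. Matched random lists had medians between -0.10 and 0.06, and each of these 8 medians lay at percentile 0 or 100 among 10000 lists. The 942 proximal-high probe sets of RA buds had medians of 0.25 in control and 0.26 in dKO, while the 2128 distal-high ones had -0.24 in dKO but 0.04 in control (percentile 93.9). Sets chosen for a large ratio on a pair of arrays shrink on other arrays through selection alone, so the smaller values outside the defining arm do not measure a loss of difference.

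The RA segments differed far more widely than those of the other arms. The SD of proximal over distal log2 ratios was 0.70 in RA, 0.36 in control and 0.34 in dKO, and it does not come from replicates. Scaling moved the balance between the segments: with a common median the control split turned to 400 proximal-high and 481 distal-high and the RA split became 1833 and 2063, and quantile normalization gave 378 and 416 in control and 1650 and 2136 in RA. The dKO counts were lower than those of control on both sides under quantile normalization (277 proximal-high and 315 distal-high against 378 and 416) and a common median (265 and 266 against 400 and 481), while as deposited the distal-high counts were close (346 and 358). With the floor at the 20th percentile the distal-high count was higher in dKO than in control (1218 against 1014).

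**Figure D2:**
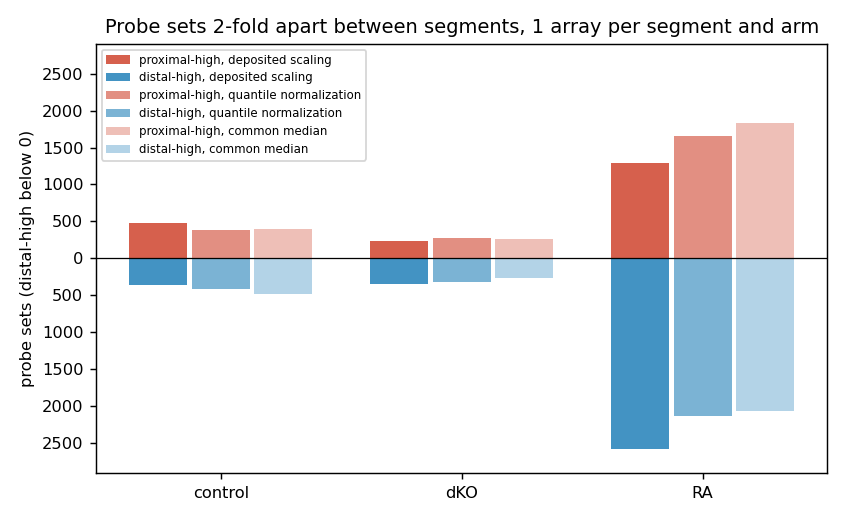
Number of probe sets at least 2-fold higher in the proximal (above 0) or distal (below 0) segment in control, dKO and RA buds, with 1 array per segment and arm; bars of lighter shade show quantile normalization and scaling to a common median. The RA bars (1296 and 2578 as deposited) exceed those of control (483 and 358) and dKO (235 and 346) under all 3 scalings.

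Probe sets that changed in dKO differed from matched lists in their shares past 2-fold between the RA segments, whose arrays took no part in the selection. Of the 691 probe sets higher in dKO in both segments, 15.5% were 2-fold proximal-high in RA and 5.79% were 2-fold distal-high. Matched random lists had medians of 6.51% and 11.7%, and the 2 shares lay at percentiles 100 and 0. Matching used the mean of all 6 arrays, dKO included, so members raised in dKO can be dimmer in RA than their matched lists. More of them can then lie at the floor on both RA arrays, where the log2 ratio is 0. How far this lowered the shares was not tested. Of the 47 lower probe sets, 25.5% were 2-fold distal-high in RA against 10.6% in matched lists (percentile 99.5), and 4.26% were proximal-high against 4.26%. Members lowered in dKO can be brighter in RA than their matched lists, which can raise such shares and was not tested either. The medians moved less: the proximal over distal log2 ratio in RA was 0 for the higher set (matched -0.07, percentile 98.97) and -0.17 for the lower set (matched -0.09, percentile 24.5), so the lower set was not set apart by its median. The alternatives moved these shares: of the higher probe sets 11.7% to 19.9% were proximal-high and 2.79% to 10.8% distal-high, and of the lower ones 7.69% to 14.6% and 15.4% to 22.2%. With the floor at the 20th percentile the lower set had 14.6% proximal-high beside 21.3% distal-high. In reverse, the 942 proximal-high probe sets of RA buds had median dKO over control log2 ratios of 0.23 in the proximal and 0.30 in the distal segment, and the 2128 distal-high ones -0.11 and 0.15. Scaling to a common median, which lowered the median distal ratio of 23428 probe sets from 0.01 to -0.34, took the distal medians to -0.17 and -0.19, still above it. The proximal RA array, which stands apart from the others, enters each of these values.

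H3K27me3 and RING1B lay together at the most strongly enriched regions of wild-type buds. With windows of a log2 of 3 or more, 3167 of 16969 tiled regions were enriched for H3K27me3, 1404 for RING1B and 1376 for both, where independent lists would share 262.0. Regions with both held a median of 37 probes and those with neither 27. A highest window tends to rise with the number of probes, so independent lists are a low reference here. Thus 98.0% of the RING1B regions also carried H3K27me3, and 43.4% of the H3K27me3 regions carried RING1B. Under normexp 554 regions had both marks and 101 RING1B alone, and these shares were 84.6% and 31.3%. With the main processing and a log2 of 1, where depleted windows outnumbered enriched ones, the shares were 61.1% and 79.2%. Which share was larger thus depended on the threshold. The share of regions with RING1B rose with the H3K27me3 window, from 11.8% at a log2 of 3 to 4, to 41.3% at 4 to 5 and 73.4% at 5 or more. Across regions, which are not independent replicates, the mean log2 ratios of the antibodies correlated at 0.740 (Pearson) and 0.641 (Spearman). Across single probes the correlations were lower, at 0.616 and 0.542.

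Regions with both marks had a median H3K27me3 mean of 3.08 and a median RING1B mean of 1.73. The 1791 regions with H3K27me3 alone had 2.08 and 0.42, and the 28 with RING1B alone had 0.83 and 0.86. Alone means under the threshold of 3 for the other antibody, not without signal. The median RING1B window was 1.96 in the 1791 regions, against 0.87 in regions with neither mark. The median H3K27me3 window of the 28 was 2.56. At the threshold of 1 set beforehand, 6900 regions were enriched for H3K27me3, 8944 for RING1B and 5464 for both, against 3637 for independent lists. Depleted windows of -1 or less numbered 9952, 12551 and 8608, so this threshold did not separate enrichment from background. At 3, depleted windows numbered 514 for H3K27me3, 1299 for RING1B and 88 for both. Depleted regions thus also coincided more often than independent lists, which would share 7361 at 1 and 39.3 at 3. With only probes well above background in both channels the depleted windows at 3 fell to 58, 14 and 1, beside 2875, 1214 and 1192 enriched regions. This filter removes probes with low ChIP signal, which make up depleted windows. The fall therefore largely follows from its construction and does not show how well the threshold separated enrichment from background. Between 86.5% and 89.4% of probes were well above background in the ChIP channel and between 92.8% and 94.4% in the input channel.

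**Figure D3:**
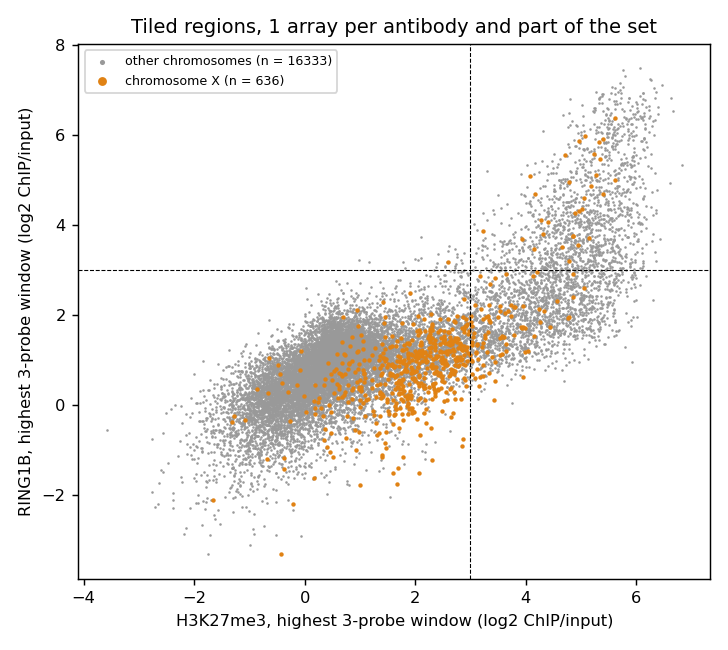
Highest window of 3 consecutive probes per tiled region for H3K27me3 (horizontal axis) and RING1B (vertical axis), as log2 ChIP over input centred on each array's median, with 1 array per antibody for each part of the probe set; orange points are the 636 regions of chromosome X and dashed lines mark a log2 of 3. The lower right holds 1791 regions with H3K27me3 alone and the upper left 28 with RING1B alone.

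The strongest regions carried both marks. The highest RING1B window, 7.49, was on chromosome 3 at 34836314 to 34844148, with an H3K27me3 window of 6.07, followed by 7.45 on chromosome 11 at 85700937 to 85708693, with 5.76. The highest H3K27me3 window, 6.83, was on chromosome 4 at 41909432 to 41922964, with a RING1B window of 5.34, followed by 6.67 on chromosome 2 at 145908065 to 145916007, with 6.55. Coordinates are those of the array design, in a build not given in the sources used here, and no annotation of that build was used, so the genes there are not named.

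Co-enriched regions joined into 1323 domains, of which 4 held over 200 probes. The widths given here are spans that include the gaps joined between regions. The domain with the most probes, 427, spanned 110.5 kb of chromosome 6 from 52085480 to 52195944 in 7 regions. The next had 318 probes in 7 regions over 100.6 kb of chromosome 15, from 102743943 to 102844504. The third had 263 probes in 5 regions over 108.2 kb of chromosome 11, from 96076182 to 96184338, and the fourth 215 probes in 2 regions over 43.1 kb of chromosome 2, from 74457946 to 74501023. The longest single region with mean ratios of at least 3 for both antibodies lay in this last domain, with a mean of 4.76 for H3K27me3 and 4.91 for RING1B over 142 probes and 27.7 kb.

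**Figure D4:**
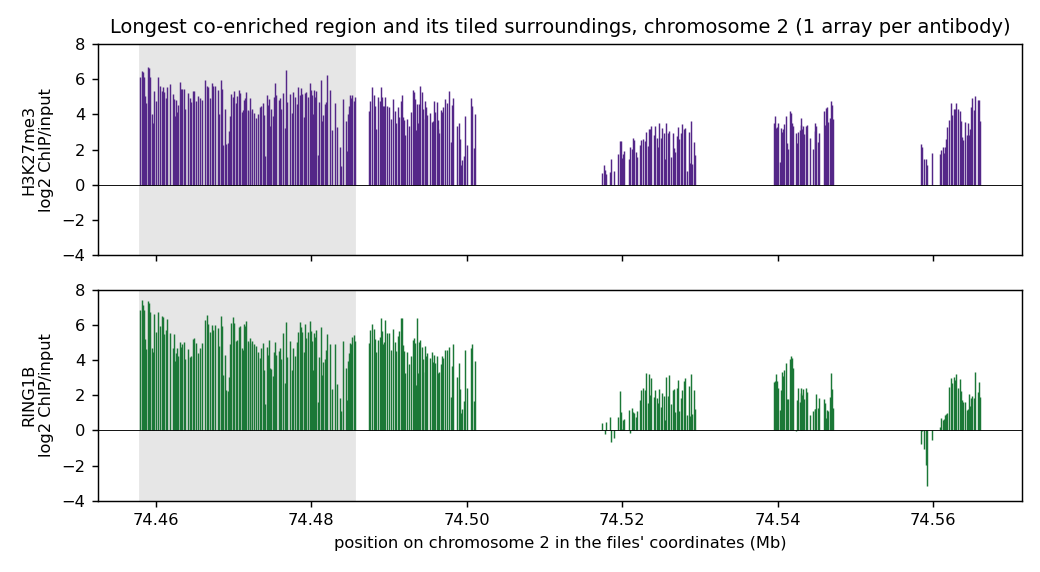
Log2 ChIP over input of each probe for H3K27me3 (upper panel) and RING1B (lower panel) along part of chromosome 2 in the files' coordinates, with 1 array per antibody; gaps hold no probes and the shaded span, 74457946 to 74485669, is the longest single region with mean ratios of at least 3 for both antibodies. Over the shaded 27.7 kb the means are 4.76 and 4.91, and the lowest windows of 3 probes are 2.17 and 1.87.

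Chromosome X carried a raised H3K27me3 level along its length. The median region mean of H3K27me3 was 1.36 over 636 regions of X and -0.45 over 7760 autosomal regions on the same array, and the 25th percentile on X was 0.90. The highest median of any single autosome was -0.09. RING1B showed no such rise, with a median of -0.47 on X and -0.21 on the autosomes of that array. Against autosomal regions of equal input signal, averaged over the arrays of both antibodies, H3K27me3 on X differed by 1.94 and RING1B by -0.01. Regions past the threshold of 3 were no more frequent on X: 17.9% of its regions (95% interval 15.0% to 21.1%) had an H3K27me3 window of at least 3, against 17.5% (16.6% to 18.3%) on those autosomes, and 5.03% (3.47% to 7.03%) had such a RING1B window, against 9.38% (8.74% to 10.05%). The threshold was the same for all regions although the H3K27me3 level of X was higher. Near-equal H3K27me3 shares therefore do not show equal numbers of peaks above the level of each chromosome. Under normexp the H3K27me3 difference between X and those autosomes was 0.22, against 1.81 as reported here and 1.63 with only probes well above background.

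**Figure D5:**
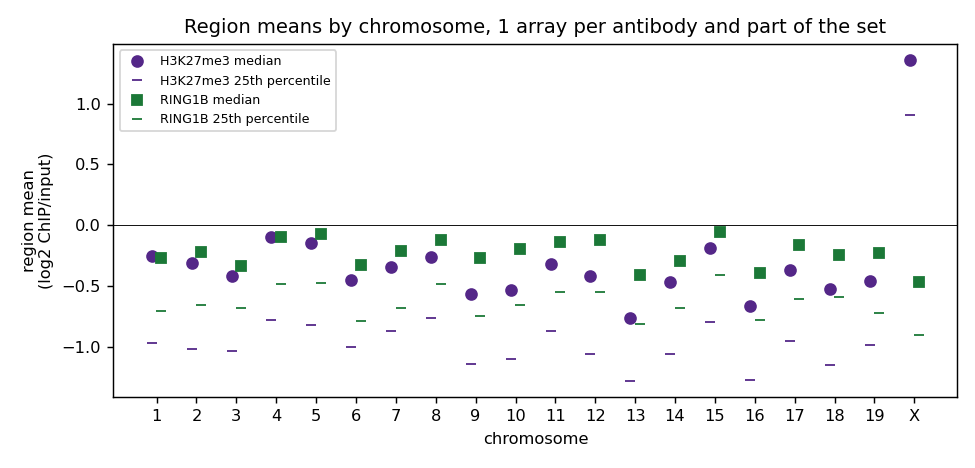
Median (filled symbols) and 25th percentile (dashes) of the region mean, as log2 ChIP over input, for H3K27me3 and RING1B on each chromosome, with 1 array per antibody for each part of the probe set. H3K27me3 on chromosome X, with a median of 1.36 and a 25th percentile of 0.90, stands above all autosomes, while RING1B on X does not.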

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

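The tests of the explanations weighed here were chosen after the result was seen; quantile normalization itself was an alternative set beforehand. The differences in direction that follow were not tested, since each group had 1 array. For dKO against control, 3 probe sets were 2-fold higher in the proximal and 2-fold lower in the distal segment, and 9 went the opposite way. For RA against control these were 7 and 44. Between arms, 6 probe sets were proximal-high in control and distal-high in dKO, and none the reverse. Between control and RA, 27 were proximal-high in control and distal-high in RA, and 4 the reverse. Between dKO and RA, 8 were proximal-high in dKO and distal-high in RA, and 10 the reverse.

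In dKO buds, 691 probe sets were higher and 47 lower in both segments. A shift of the whole signal distribution would have brought the share higher to near 50% after quantile normalization, and it was 88.1%. An additive background common to all probe sets would have raised the 27 bacterial control probe sets, which have no target in mouse RNA, and their median signal was at most 1.17 times that in control. Among the changed probe sets above the 60th percentile on all 4 arrays, 82.6% were higher (95% interval 73.3% to 89.7%), against unequal noise at dim signals for that part. Noise specific to dim probe sets remains open for the rest (the 10th percentile of signals was 5.57 and 5.39 on the dKO arrays and 3.30 and 4.24 on the control arrays). A difference other than genotype between the dKO and control samples, common to both segments, remains open too. The loss of RING1B, with that of RING1A if the control buds were wild type, remains open as the biological explanation, untested because expression could not be joined to ChIP.

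The proximal RA array stood apart from the other 5. A different signal range would have gone with quantile normalization, after which the SD of proximal over distal ratios in RA was still 1.98 times that in control. A batch effect acting alike on both RA arrays, which the dim bioB controls of both point to, would cancel within the RA arm, where the SD was 1.93 times that in control. That ratio is the wider spread between RA segments itself, so it does not bear on a batch effect acting unequally on the 2 arrays. Poorer RNA would raise the 3' over 5' ratio of control transcripts. This ratio was highest on the proximal RA array for 2 of 4, Gapdh (1.60) and beta-actin (1.95). It was not for the transferrin receptor or pyruvate carboxylase, but their 5' signals there, 14.6 and 11.9, were under the floor. Their ratios therefore say little about RNA quality. The Gapdh and beta-actin 5' signals on that array were 10846 and 8259, so their ratios could be measured. On the other arrays these ratios ran from 1.28 to 1.39 and from 1.52 to 1.72. The differences had the direction of poorer RNA but were small. The brightest signals also reached higher on the proximal RA array, and whether this moved the ratios was not tested. RNA quality, a batch effect unequal between the RA arrays and an effect of RA in the proximal segment cannot be told apart, because that segment had 1 RA array.

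H3K27me3 region means were high along chromosome X. A copy number, labelling or amplification bias shared by both antibodies would have raised RING1B too, and its difference was -0.26 from the autosomes of the same array and -0.01 from those of equal input signal. Input signals on X, averaged over the arrays of both antibodies, had a median difference of -0.45 from those autosomes. Dim input common to both antibodies would leave no difference against autosomal regions of equal averaged input, and that difference was 1.94. Input dim on the H3K27me3 array alone could survive this match, so it is not excluded. With only probes well above background the difference from the autosomes of that array was 1.63, but under normexp it was 0.22. Its size thus depends on the processing. The normexp alternative used median spot signals in place of processed signals, another background correction and an offset. The parts of these changes were not separated. An inactive X in female embryos of the pool remains open as the biological explanation and was not tested, and the sexes in the pool are not given in the sources used here.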

How the results depend on the processing

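Alternatives for expression changed the sizes of lists and, for some comparisons, the balance of directions, and the causes were not tested. The control split between segments turned from 483 proximal-high and 358 distal-high to 378 and 416 with quantile normalization and 400 and 481 with a common median, which also evened out the splits of RA against control (451 and 450) and between dKO segments (265 and 266). No analysis paired by replicate number was possible, because each group held 1 array. A fit over the 6 arrays with segment as a block was not run, since its residual would hold the segments' different responses and not a replicate spread. The median over a gene's probe sets and all gene lists were not run. A common median moved the median dKO ratio of 23428 probe sets to -0.21 (proximal) and -0.34 (distal), from -0.02 and 0.01.

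Of the recomputed counts, 39 lay within 1.5 times of the reported ones and 53 did not. The 39 include those from the authors' ChIP value table, which holds the same ratios and could not differ. Quantile normalization gave 17 higher probe sets shared by dKO and RA. A common median gave 453 higher and 90 lower in dKO, and 14 higher and 21 lower shared with RA. The floor at the 20th percentile gave 1300 higher and 89 lower in dKO, 976 and 513 in RA, and 113 and 20 shared; its proximal-high and distal-high counts were 1351 and 1014 in control, 951 and 1218 in dKO, and 3323 and 4295 in RA. The floor at the 60th percentile gave 179 and 26 in dKO, 212 and 141 in RA, and 4 higher shared; between segments it gave 152 and 130 in control, 60 and 101 in dKO, and 575 and 1276 in RA. These smaller counts follow from its construction, since every probe set it called in dKO or RA was among those called with the lower floor. The 3-fold threshold gave 239 and 15 in dKO, 122 and 77 in RA, and 6 and 3 shared; between segments it gave 136 and 86 in control, 28 and 61 in dKO, and 288 and 730 in RA. The distal arrays alone, chosen after seeing the data, gave 1905 and 736 in RA.

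Of the dKO-higher probe sets, 517 of 691 were also called with quantile normalization and 453 with a common median; all 47 lower ones were called with either. The 36 correlations recomputed moved by under 0.1, but 3 changed sign, all between dKO and RA across segments: -0.0319 and -0.0039 with quantile normalization and, for dKO distal with RA proximal, -0.0596 with the floor at the 60th percentile. The 80 recomputed ratios of the leading probe sets kept their direction and a 2-fold size, but with the floor at the 60th percentile 12 of 20 were over 1.5 times smaller in fold. Of 80 set medians, 40 moved by under 0.1 and kept their sign where matched lists set them apart, 35 moved by more, and 5 of those set apart changed sign. Among the 35, probe sets proximal-high in RA fell from 0.23 to 0.0025 in dKO proximal with a common median, and those distal-high in RA went from 0.04 to -0.0669 in control. A common median shifts all probe sets of a comparison alike, in dKO distal and RA distal to medians of -0.34 and -0.20, so a sign changed by it does not show that a set moved against the others. With it, probe sets proximal-high in dKO had -0.0599 in RA distal, those proximal-high in RA -0.17 in dKO distal, and those distal-high in RA -0.19 in dKO distal. With the floor at the 20th percentile, probe sets distal-high in dKO had 0.0934 in RA distal, and at the 60th those proximal-high in dKO had -0.0377. Of 16 shares of dKO-changed probe sets by RA segment, 6 moved beyond their interval. Of the higher probe sets, 19.3% were proximal-high with quantile normalization, 19.9% and 10.8% were proximal-high and distal-high with the 20th percentile floor, and 11.7% and 2.79% with the 60th. Of the lower ones, 14.6% were proximal-high with the 20th.

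For ChIP, normexp gave 4225 H3K27me3, 3134 RING1B and 2318 shared regions at the threshold of 1, and 1771, 655 and 554 at 3. A threshold of 1.5 gave 4610 RING1B and 3409 shared regions. The threshold of 3, chosen after seeing the data, gave 3167, 1404 and 1376. The authors' value table gave the same enriched counts at both thresholds, since it holds the same ratios, so it is no separate check. Windows of 5 probes and probes well above background kept the counts at both thresholds within 1.5 times. Normexp lowered the chromosome X difference for H3K27me3 from 1.81 to 0.22, while probes well above background gave 1.63. For RING1B these were -0.08 and -0.09, from -0.26.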

Other observations

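The test described here was chosen after the result was seen. The 4 co-enriched domains with the most probes lay on chromosomes 6, 15, 11 and 2. In the RefSeq table of GRCm38.p6, the Hoxa, Hoxb, Hoxc and Hoxd clusters, which hold the homeobox genes that pattern the limb and body axis, lie on chromosomes 6, 11, 15 and 2, with 11, 10, 9 and 9 genes. When 4 of the 1323 domains were drawn at random 100000 times, 0.026% of draws fell on all 4 of these chromosomes. With domains joined over 10 kb or 50 kb the 4 largest again lay on them, in 0.034% and 0.027% of draws. The 4 domains with the most probes may therefore be the Hox clusters. This rests on chromosomes alone, since the builds may differ and no positions were compared.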
